A study of Mus musculus with 2 samples.

How the data were processed

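The series studies mouse retina with SeekSpace, a method that gives each nucleus of a tissue section a gene expression profile and a position on a chip. Per the labels, 2 libraries came from 1 section of 10 micrometres from 1 eye: an expression library and a library of spatial barcodes, both named T1. The design text names mice heterozygous for a missense allele of Prph2 and age- and sex-matched wild types, with spatial data at 6 months. It leaves T1 without a genotype, so both samples have no group, no genotype comparison was made, and no genotype was inferred from the values. No paired analysis was possible because the samples have no groups to pair.

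The deposited expression matrix holds raw UMI counts, a count of molecules per gene and barcode: its values were whole numbers, with totals that differed widely between barcodes. The deposited position table holds 1 point per barcode, in other units whose length is not given in the sources used here. The deposited feature table holds Ensembl identifiers and gene symbols. The submitters' processing notes name fastp, STAR, Seurat 4.1.1 and the build mm10. Their roles, the annotation release, the strand setting, whether introns were counted and how cells were called are not given in the sources used here. A gene with an opposite-strand neighbour (Fgf2, Vax2) or a close paralogue (C4b and C4a) is therefore uncertain by the share of reads that could belong to either. Gene positions came from RefSeq's annotation of GRCm38.p6, the assembly that mm10 names, matched by symbol.

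Computation used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Nuclei were kept with at least 200 detected genes and under 10% of UMIs from mitochondrial genes. Scrublet, a doublet caller, was then run with a fixed seed. It marked 0 nuclei, which allows a share of up to 0.0178% (3 counts of the total); a share under 0.5% was set as the sign that it had not worked, so doublets remain among the nuclei. Counts were normalised to 10000 per nucleus and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave the clusters. The 51 list and ligand or receptor genes that would have been among the variable genes, and were not cell type markers, were left out of clustering, so that their levels did not form the clusters. Clusters were named from fixed marker lists alone, as "rod-like" and so on, when at least 3 markers led the cluster.

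Levels are CPM, the UMIs of a gene over all UMIs of a class on the customary CPM scale, pooled over the nuclei of the class, with exact Poisson 95% intervals. Shares carry exact (Clopper-Pearson) binomial 95% intervals. Both cover counting error only, since 1 section has no replicates and nuclei are not replicates, and no p-value was computed. A gene was called class-high when the lower bound of its highest class was at least 2 times the upper bound of every other named class of at least 50 nuclei, and not measured under 20 UMIs. A ligand-receptor pair was called measured when ligand and receptor each had a lower bound of at least 10 CPM and at least 20 UMIs. Neighbourhood enrichment is the share of a class among the 20 nearest nuclei over its share among all kept nuclei. Within a class, Moran's I (10 nearest nuclei of the class) measured how alike neighbours were, for genes detected in at least 5% of its nuclei. A list's median Moran's I was set against 10000 random lists matched on mean expression in 20 bins. Opsin shares were taken in 8 sectors from k-means on the coordinates.

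These filters, rules, lists and most alternatives were chosen before the data were examined. The 15 lists cover the outer segment disc and axoneme, phototransduction, photoreceptor transcription, the retinoid cycle, phagocytosis and lysosome, Müller gliosis, microglial activation, complement, the ribbon synapse, glycolysis and lactate transport, the unfolded protein response, cell death, immediate early genes, dorsoventral position, and tight junction and polarity. A further list holds 56 ligand-receptor pairs. Named genes are Prph2, Rom1 and the cone opsins, up to 4 class-high members per list in order of the ratio to the next class, up to 12 measured pairs per sender in order of the smaller level, and the 10 genes of highest Moran's I in rod-like, Müller-like and bipolar-like nuclei. Of the list symbols, Des1, Clec7a, Vglut1 and Pals1 were not among the features under those names. Results for some named genes are not reported here.

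Several choices were made after the data had been seen. A cluster was left unnamed when the second score exceeded 0.48 of the best, at first 0.5, or when its best score was under 0.7. The change left cluster 31 (577 nuclei with bipolar and Müller markers) and cluster 21 (261 nuclei led by adipocyte genes) unnamed. Cluster 31 made up 4.22, 2.75, 3.76 and 2.98% of the nuclei of pieces 1 to 4, and cluster 21 made up 0.673, 1.28, 0.677 and 3.35%. The nuclei lay in 4 ring-shaped pieces of tissue, and the borders between them were set at gaps in the positions. Of 4 versions of that rule, the last, with a search window of 3500 coordinate units, was adopted when values per piece had already been seen. Depth is the distance inward from the ring of RPE-like nuclei of a piece, and nuclei from −100 to 1200 form the retinal band. Rod cluster 5 (318 nuclei, with more markers of another class than of rods among its 10 leading genes) was left out of gene levels per piece, except those of Xist and the Y-linked genes given for each piece and of Vax2 in the parts of a piece, and made up 2.22, 1.69, 1.33 and 2.19% of the pieces.

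The rules were tested on simulated data with the totals of these classes. Of 100 genes raised 3-fold in 1 class, the class-high rule recovered 6, and of 100 raised 6-fold it recovered 45; among those with at least 200 UMIs in that class it recovered 5 of 37 and 34 of 43. A gene that differs by less than several-fold is therefore often missed. Of 18398 simulated genes, the changed ones included, the rule called 0 of those left unchanged. Unchanged genes had the same rate in every class with counting error only. This gives no rate of false calls for the real data. Among 148 testable genes made to differ 3-fold between the left and right of the chip, 131 reached the top 200 of 4106 by Moran's I. Genes that this change took under 5% detection were not counted. The contrast ran across the chip and not within each piece.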

Results

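The data describe nuclei of mouse eye tissue, labelled as 1 section, each with its expression profile and a position on a chip. The expression library held 17285 barcodes, 32285 features and 55843593 UMIs, with a median of 1771 UMIs and 1022 genes per barcode. Every barcode had a position. After filtering, 16867 nuclei remained, with a median of 1811 UMIs and 1042 genes; 328 barcodes had under 200 genes and 97 had at least 10% mitochondrial UMIs. The non-coding transcript Gm42418, which overlaps ribosomal RNA sequence, took 8.34% of UMIs. The values come from 1 library with no replicates.

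Which cell classes the section held was asked first. Rod-like nuclei formed the largest class, at 34.7% of kept nuclei (95% interval 34.0 to 35.4%). Shares are of kept nuclei and need not be those of the tissue. Rod-like nuclei had the lowest median of the classes, at 1059 UMIs. Their share was 34.4% with at least 500 genes, but loss of nuclei before the deposited barcodes were called was not tested. Amacrine-like interneurons made up 12.1%, bipolar-like interneurons 8.14%, cone-like photoreceptors 3.69%, Müller glia-like nuclei 3.39%, ganglion cell-like nuclei 2.34% and horizontal-like nuclei 0.320%. The retinal pigment epithelium (RPE), which renews visual pigment and takes up shed outer segments, made up 3.92% (3.64 to 4.23%). The section also held tissue around the retina. Fibroblast-like nuclei made up 9.33%, vascular 5.19%, skeletal muscle 2.73%, microglia or macrophage 2.51%, lens 1.49%, melanocyte 1.47%, myelinating glia 1.05% and surface epithelium 0.368%. Of 39 clusters, the 4 unnamed ones, 21, 29, 31 and 36, held 1224 nuclei (7.26%). Unnamed nuclei made up 7.31, 6.63, 7.69 and 7.42% of the nuclei of pieces 1 to 4, and with the first naming thresholds, which named clusters 21 and 31, the bipolar share was 11.6%. The order of the interneurons turned at resolution 0.5 (bipolar 11.6%, amacrine 8.72%) and with at least 500 genes (10.9 and 9.77%). At resolution 0.5 no cluster was named Müller glia.

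Where the classes lay was asked next. Nuclei lay in 4 ring-shaped pieces of tissue, with 4457, 4145, 3695 and 4570 nuclei, while the labels describe 1 section of 1 eye. Classes followed the layers of the retina inward from the RPE. Depths are of nuclei in the retinal band, itself a cut on depth. The band held 66.0% of rod-like and 67.5% of bipolar-like nuclei at angles covered by RPE-like nuclei. Over the pieces together, median depth in coordinate units was 88.6 for cone-like, 159.9 for rod-like, 387 for bipolar-like, 403 for Müller-like, 516 for amacrine-like and 733 for ganglion cell-like nuclei. Pieces differed in the depth of rod-like nuclei in the band, with medians of 228, 99.9, 139 and 163 in pieces 1 to 4. Rod-like nuclei per inner retinal nucleus (amacrine, bipolar, Müller, horizontal or ganglion cell-like) in the band were 1.16, 1.03, 0.617 and 1.76. Over all nuclei of a piece they were 1.26, 1.38, 0.875 and 1.99, which turns the order of pieces 1 and 2; the band held 78.7, 57.8, 56.8 and 66.1% of rod-like nuclei at covered angles.

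**Figure D1:**
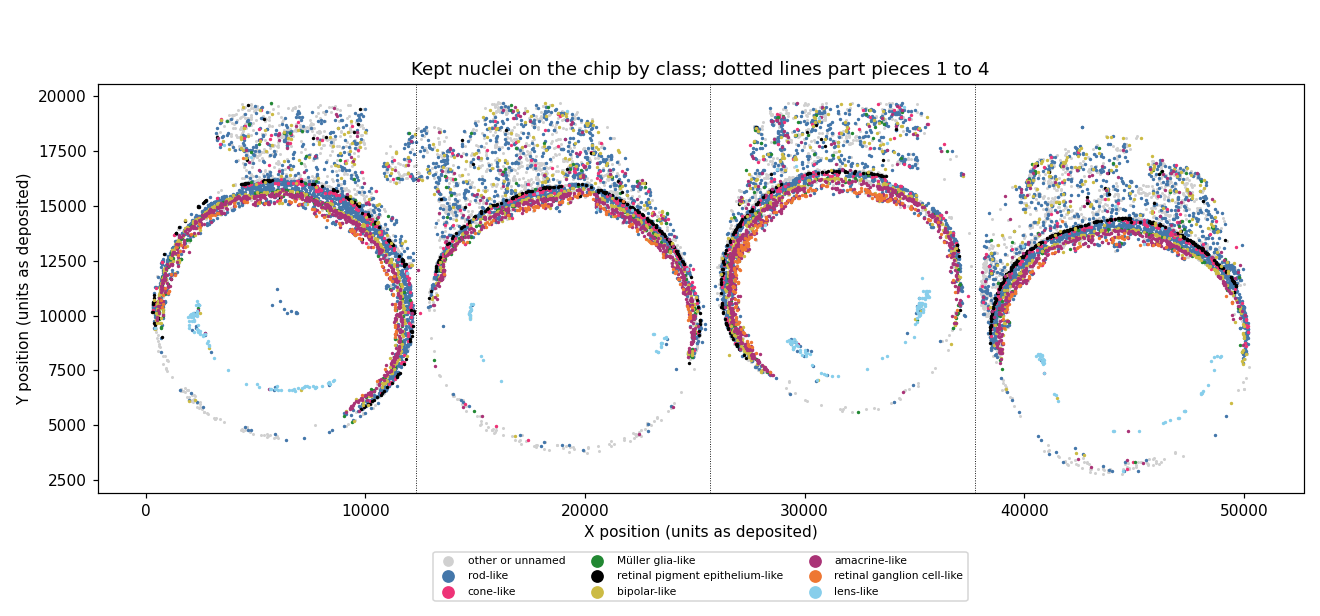
Position of each kept nucleus on the chip in the deposited coordinates, coloured by class. The nuclei lie in 4 ring-shaped pieces, with RPE-like nuclei around the retinal layers.

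**Figure D2:**
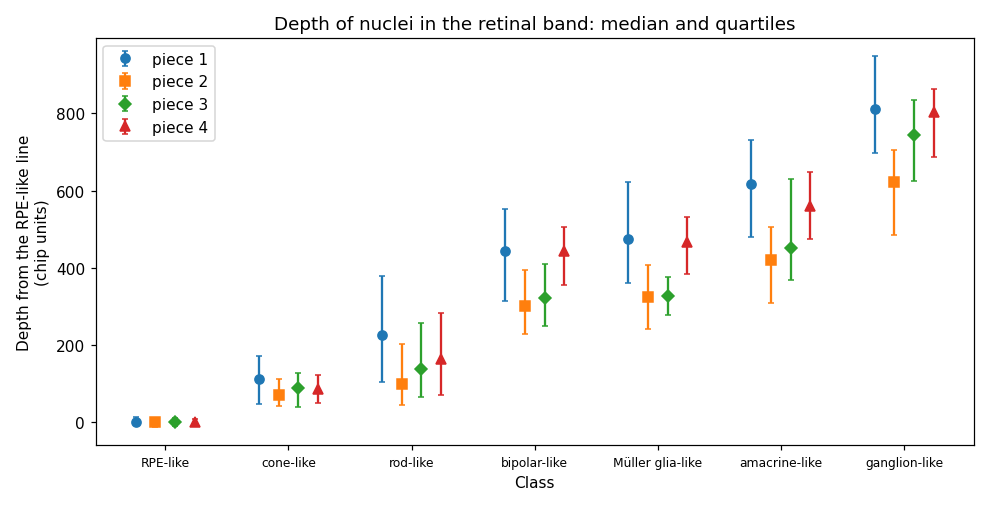
Depth inward from the ring of RPE-like nuclei, in coordinate units, for nuclei of each retinal class in the retinal band of each piece. Cone-like and rod-like nuclei lie next to the RPE, and ganglion cell-like nuclei lie deepest.

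Neighbours on the chip showed the same order. RPE-like nuclei had RPE-like neighbours 4.29 times as often as their share (3.12 to 5.01 in the pieces), and rod-like nuclei had rod-like neighbours 1.36 times as often (1.32 to 1.39). Cone-like nuclei lay beside rod-like nuclei at 1.47 times and beside RPE-like nuclei at 2.14 times. Ganglion cell-like nuclei lay beside amacrine-like nuclei at 3.19 times (2.31 to 4.63). Müller-like nuclei, whose cell bodies sit among the interneurons, lay beside bipolar-like nuclei at 1.91 and amacrine-like nuclei at 1.89 times. Of rod-like nuclei at angles covered by RPE-like nuclei, 66.0% lay in the retinal band, against 98.4% of ganglion cell-like nuclei.

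Prph2, the tetraspanin that shapes the rims of outer segment discs and the gene altered in the series' mutant mice, was high in both photoreceptor classes. Prph2 (ENSMUSG00000023978, chromosome 17, 46910478 to 46924933, GRCm38.p6) reached 2317 CPM (2284 to 2349) in 5857 rod-like nuclei and 2334 CPM (2280 to 2389) in 623 cone-like nuclei. At least 1 Prph2 UMI was found in 85.3% of rod-like and 83.3% of cone-like nuclei, against 10.4% of ganglion cell-like nuclei, whose median depth was 8223 UMIs against 1059 in rod-like nuclei. In the other named classes Prph2 lay between 23.9 CPM in ganglion cell-like and 196 CPM in lens-like nuclei. Whether these lower levels came from free RNA, doublets or the nuclei themselves was not tested. Its partner Rom1 (chromosome 19, 8927382 to 8929356) reached 377 CPM (364 to 390) in rod-like and 523 CPM (497 to 549) in cone-like nuclei. Elsewhere Rom1 lay between 12.6 CPM in horizontal-like and 97.3 CPM in RPE-like nuclei. Neither gene was class-high, since the photoreceptor classes shared it.

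The lists were read across classes. Of 187 list entries, 180 were measured and 27 were class-high, being 26 genes of 177. Of the 17 measured members of the Müller gliosis list, 3 were class-high: Cp, the iron oxidase ceruloplasmin, in Müller-like nuclei at 1004 CPM (957 to 1054), Ednrb in melanocyte-like nuclei at 906 CPM, and Cntf in myelinating glia-like nuclei at 95.4 CPM. Of 11 measured members of the microglial activation list, 6 were class-high, 4 of them in microglia or macrophage-like nuclei, 1 in melanocyte-like and 1 in skeletal muscle-like nuclei. Cd68, a lysosomal protein of phagocytes, reached 241 CPM in microglia or macrophage-like nuclei against 44.6 CPM in the next class. Tyrobp, Trem2 and Itgax stood at 101, 104 and 106 CPM in the same nuclei and at 4.75, 6.09 and 2.03 CPM in the next class, where 1 to 3 UMIs were seen. The complement list had 2 of 9, both in fibroblast-like nuclei: C3 at 469 CPM (444 to 495) and the C1 inhibitor Serping1 at 622 CPM (594 to 652).

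In the retinoid cycle list 4 of 11 measured members were class-high. Rdh10 stood at 1153 CPM (1119 to 1189) and Degs1 at 157 CPM (145 to 171) in RPE-like nuclei, while Rbp3, the retinoid carrier between RPE and photoreceptors, was led by cone-like nuclei at 3144 CPM against 1136 CPM in rod-like nuclei. The phagocytosis and lysosome list had 3 of 14. Itgav, an integrin that binds outer segments, stood at 865 CPM and Tyro3 at 86.6 CPM in RPE-like nuclei, and Anxa2 at 1424 CPM in surface epithelium-like nuclei. Glycolysis and lactate transport had 2 of 14, both RPE: the lactate transporter Slc16a1 at 722 CPM (695 to 750) and its partner Bsg at 1833 CPM (1789 to 1878). The dorsoventral position list had 1 of 11, Bmp4 at 212 CPM in RPE-like nuclei. Of 9 photoreceptor transcription genes, 1 was class-high, Otx2, at 588 CPM in RPE-like against 247 CPM in bipolar-like nuclei.

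Among the remaining lists, tight junction and polarity had 3 of 10 measured members class-high: Cdh3 in RPE-like nuclei at 399 CPM, Cldn19 in myelinating glia-like nuclei at 331 CPM, and Crb1, an apical polarity protein, in Müller-like nuclei at 1119 CPM (1069 to 1171). Crb1 was also the 1 class-high member of 14 in the outer segment disc and axoneme list. The unfolded protein response list had 1 of 14, Chac1 in surface epithelium-like nuclei at 413 CPM. Class-high members numbered 0 of 15 for phototransduction, 0 of 12 for the ribbon synapse, 0 of 12 for cell death and 0 of 7 for immediate early genes. Rod-like and cone-like nuclei are separate classes, so a gene at like levels in both cannot be called. The count of class-high genes was 16 when each nucleus was thinned to 500 UMIs and 14 with a rule of 3 times, and reached 39 at resolution 2 and 37 with at least 500 genes.

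The title of the series asks about signals from RPE and Müller glia toward photoreceptors, so ligand levels in these senders were set beside receptor levels in rod-like and cone-like nuclei. Of 56 pairs, 15 were measured from Müller-like nuclei and 12 from RPE-like nuclei, and 11 were measured from both. All 15 and all 12 were measured toward rod-like nuclei and also toward cone-like nuclei. The receiver named with a pair below is therefore not the only one. Adhesion molecules led from Müller glia. Cadm1 stood at 3184 CPM in Müller-like nuclei and 2382 CPM in rod-like nuclei, Ncam1 at 3214 and 1400 CPM, Negr1 at 514 and 1794 CPM, and Cadm2 at 1727 CPM beside its partner Cadm1. Cone-like nuclei held Negr1 at 2564 CPM. Müller-like nuclei also held Cdh2 at 2004 CPM beside 314 CPM in cone-like nuclei. The growth factor Ptn stood at 398 CPM in Müller-like nuclei beside its receptor Sdc2 at 111 CPM in cone-like nuclei. The dystroglycan ligands Agrn, Lama1 and Egflam stood at 171, 128 and 53.1 CPM in Müller-like nuclei, with Dag1 at 94.9 CPM in cone-like and 68.9 CPM in rod-like nuclei.

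From the RPE, the lipid carrier Apoe led. Apoe stood at 1550 CPM (1510 to 1591) in RPE-like and 1131 CPM (1080 to 1183) in Müller-like nuclei, with its receptor Vldlr at 343 CPM (323 to 365) in cone-like nuclei. The growth factors Bmp4 and Igf2 stood at 212 and 194 CPM in RPE-like nuclei, with Bmpr1a at 322 CPM and Igf1r at 1135 CPM in rod-like nuclei. Nectin1 stood at 160.0 CPM in RPE-like nuclei beside Nectin3 at 24.5 CPM in rod-like nuclei. Of the 12 pairs from RPE-like nuclei, 7 were measured at a minimum of 50 CPM. Levels of transcripts in nuclei do not show that a ligand reached its receptor. Free RNA may add to the low ones, and its share was not estimated.

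Variation across the tissue was asked of the cone opsins first, since mouse cones carry more short-wavelength opsin Opn1sw ventrally and more medium-wavelength opsin Opn1mw dorsally. With sector 1 left aside, the share of Opn1sw among opsin UMIs in cone-like nuclei ran from 19.5% (17.5 to 21.5%, 96 nuclei) in sector 8 to 70.1% (67.8 to 72.4%, 101 nuclei) in sector 5. Sector 1, with only 12 cone-like nuclei, gave 11.6% (6.66 to 18.5%). The remaining sectors 2, 3, 4, 6 and 7 gave 34.1, 60.0, 35.3, 38.6 and 44.5%. Sectors can mix pieces: only 55.1% of the nuclei of sector 5 lay in its main piece, piece 3. With 4 sectors, the lowest share was 30.7%. Each piece, split in the band at the centre of its ring into a left and a right part, showed the contrast. The left and right shares were 16.4 and 59.7% in piece 1, 13.1 and 71.0% in piece 2, 60.9 and 12.0% in piece 3 (15 cone-like nuclei on the right), and 50.8 and 16.9% in piece 4. Vax2, a ventral transcription factor, stood in all rod-like nuclei of the left and right parts, cluster 5 included, at 28.8 and 125 CPM in piece 1, 20.002 and 164 CPM in piece 2, 145 and 35.0 CPM in piece 3 (4 UMIs on the right), and 172 and 28.4 CPM in piece 4.

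Genes that varied from place to place within a class were ranked by Moran's I. It was computed over all pieces together, so a difference between pieces raises it as variation within a piece does. The values below, those of the lists included, do not separate these. In Müller-like nuclei, after Xist (0.474), the complement gene C4b (0.298, uncertain against its paralogue C4a), Gm29683, the retinoic acid hydroxylase Cyp26b1, the glutamate receptor Grik3, the glial filament gene Gfap, A2m, Foxp2, Chst9 and Efnb2 followed. Lists with members tested in Müller-like nuclei were set against random lists. The Müller gliosis list had a median of 0.0395 against 0.00312 (percentile 100, 9 members), the complement list 0.133 against 0.00136 (percentile 100, 3 members, C4b being in both), the dorsoventral list percentile 99.99 and the immediate early list percentile 99.71. In rod-like nuclei, Xist (0.288), B3galt1 (0.261), Nav1, Antxr2, Zbtb7c, 9330159M07Rik, Myo5b, Vax2os, Klhl29 and Gnb3 led. No tested list in rod-like nuclei passed percentile 96.9, that of the unfolded protein response. The phototransduction, photoreceptor transcription and outer segment lists stood at percentiles 41.29, 4.46 and 25.76 in rod-like, 98.62, 97.64 and 96.32 in bipolar-like, and 7.32, 46.78 and 97.71 in Müller-like nuclei. In bipolar-like nuclei Xist (0.434) stood far above Vax2 (0.0635), Plch1, Fam171a1, Smyd3, Frrs1l, Klhl29, Spink13, Smcr8 and the Y-linked Uty (0.0494), and 3 to 6 of these 10 stayed in the top 10 under other settings.

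Several of the leading genes differed many-fold between the pieces. In Müller-like nuclei of the band, C4b stood at 55.9, 576, 436 and 51.2 CPM in pieces 1 to 4, and Grik3 at 101, 642, 428 and 87.0 CPM. Gfap had 4, 5, 21 and 0 UMIs. In rod-like nuclei of the band, B3galt1 stood at 118, 989, 1122 and 64.3 CPM, Nav1 at 198, 867, 903 and 141 CPM, Antxr2 at 88.9, 648, 526 and 86.0 CPM, Zbtb7c at 38.8, 286, 425 and 15.3 CPM, and Myo5b at 30.8, 345, 426 and 26.1 CPM. Gnb3, a transducin subunit of cones and bipolar cells, stood at 80.2, 361, 355 and 66.2 CPM in rod-like nuclei. Cyp26b1 followed another order in Müller-like nuclei, with 66, 3, 0 and 6 UMIs. No piece has a group in the labels, so these values are given side by side.

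**Figure D3:**
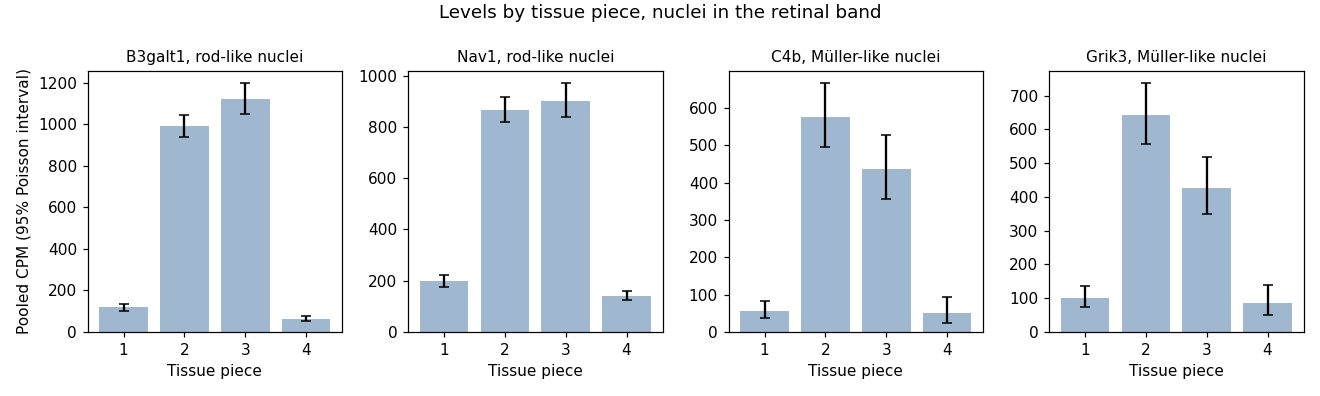
Pooled CPM of B3galt1 and Nav1 in rod-like nuclei and of C4b and Grik3 in Müller-like nuclei of the retinal band, for each of the 4 pieces, with exact Poisson 95% intervals. C4b stands at 55.9, 576, 436 and 51.2 CPM in pieces 1 to 4.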

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

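Alternatives that removed the nuclei of highest Scrublet scores, kept only the retinal band, changed the naming thresholds or concerned Fgf2 between pieces or rods per inner nucleus were chosen after seeing the data, and the others beforehand. Of 168 alternative values for 25 results, 101 stayed within the main value's interval (counts within 1.5 times) and 67 moved beyond it. For neighbours, the range over the pieces served as the interval. The cause was not tested. Keeping the nuclei that Scrublet marked changed nothing, since it marked 0, and says nothing of stability. Its values repeat the main ones and are among the 101. With the list genes kept for clustering, the rod share was 33.3% and Prph2 in rods 2169 CPM. Without the 5% of highest Scrublet scores they were 36.3% and 2268 CPM. In the band alone the rod share was 37.2%, Müller 4.28%, RPE 6.20%, Prph2 2375 CPM, rod beside rod 1.45, RPE beside RPE 3.00, and the highest and lowest Opn1sw shares 73.6 and 18.9%. With at least 500 genes, Müller was 3.70%, RPE 3.33%, Prph2 2258 CPM and the lowest Opn1sw share 20.8%. Müller was 0% at resolution 0.5 and 3.11% at resolution 2. Prph2 was 2387 CPM with 15 components, 2233 CPM as a mean over nuclei, 2394 CPM with totals without mitochondrial genes and the 12 rod markers, and 2260 CPM after thinning to 500 UMIs. Class-high genes numbered 16 after thinning and 14 at 3 times, and RPE pairs 7 at 50 CPM. With 10 and 50 neighbours, rod beside rod was 1.46 and 1.23 and RPE beside RPE 5.27 and 3.04. The highest Opn1sw share was 55.3% with 4 sectors and 77.9% with 12, and the lowest 30.7% with 4. Lowest shares were set against the 11.6% of sector 1, which had only 12 cone-like nuclei. Against sector 8, at 19.5% (17.5 to 21.5%), the 18.9 and 20.8% would have stayed within the interval. Fgf2 in rods, highest over lowest piece, was 4.78 after thinning and 4.11 with all rods of a piece. Of the top 10 genes by Moran's I, 8 to 10 stayed in rod-like and in Müller-like nuclei. Thinning left out 244 of 5857 rod-like and 12 of 572 Müller-like nuclei. Counts per piece in Müller-like nuclei were as low as 0 UMIs for Gfap and Cyp26b1.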

Other observations

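The tests of position error, 1 eye, depth, part of the retina, sex, free RNA and caught rods were chosen after the results had been seen, and Fgf2, Edn2, Zbtb7c, B3galt1, Myo5b, Dcc, Gnb3 and Stat3 in rod-like nuclei were first picked from a screen of the genes that differed most between pieces. They are therefore its high end: among 4215 genes with at least 200 UMIs in rod-like nuclei of the band, whose median ratio of the highest to the lowest piece was 1.28, Zbtb7c ranked 2, B3galt1 5, Myo5b 6, Edn2 12, Dcc 14, Fgf2 18, Gnb3 21 and Stat3 45. Prph2 ranked 603. To avoid that choice, 47 genes were taken whose highest piece exceeded the lowest by over 2 times, between the bounds of their intervals, in a random part of these nuclei. In the remaining 1709 nuclei their median ratio between the same pieces was 4.30 (95% interval of the median 3.76 to 6.23), and 46 of them exceeded 2. Both parts of the nuclei came from the same pieces, so the split removes only the counting error of the choice. The interval is over genes, taken as independent, and covers no spread between pieces or animals.

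Among the picked genes, Fgf2, a growth factor, stood at 92.3, 412, 350 and 63.1 CPM in rod-like nuclei of pieces 1 to 4, and Edn2, an endothelin, at 10.0, 87.5, 74.8 and 6.4 CPM. Stat3 stood at 84.2, 287, 281 and 86.0 CPM in rod-like and 103, 272, 241 and 102 CPM in Müller-like nuclei. Dcc ran the other way, at 275, 31.6, 48.6 and 228 CPM in rod-like nuclei. In these genes, and in C4b and Grik3, pieces 1 and 4 lay apart from pieces 2 and 3, and no genotype was assigned to any piece. The Fgf2 ratio of the highest to the lowest piece was 6.54, with 5.84 when all rod clusters were kept and 4.11 (3.53 to 4.81) with the rod-like nuclei outside the band included. Borders drawn in 3 other ways gave 6.48, 5.93 and 6.54; piece 4 was the same in each, and the first, which merged pieces 1 and 2, gave 284, 342, 409 and 63.1 CPM. The Müller gliosis list in Müller-like nuclei had a median log2 level against the mean of the pieces of −0.31, 0.22, 0.52 and −0.41 (7 members).

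Prph2 stood at 2530, 2067, 1805 and 2809 CPM and Rom1 at 482, 313, 274 and 503 CPM in rod-like nuclei of pieces 1 to 4, while Sag stood at 6170, 8486, 7631 and 6014 CPM. The median log2 level of the 12 rod markers was 0.19, −0.10, −0.43 and 0.33. Rod cluster 6 had Fgf2os and Edn2 among its 10 leading genes, and rod cluster 9 the adipocyte genes Fabp4, Nrg4 and Cdo1. Sex-linked transcripts parted the pieces in another way: in rod-like nuclei of the band Xist stood at 41.2, 24.9, 32.0 and 943 CPM, and 4 Y-linked genes together at 217, 234, 201 and 19.2 CPM.

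Rod-like nuclei placed outside the retinal band form the first pattern weighed. Outside the band the highest piece exceeded the lowest in Xist by 1.57 times (1.26 to 1.96), against 37.9 times (27.2 to 54.7) inside it, which is consistent with position errors that carry nuclei between pieces. RNA fully mixed within nuclei is argued against: nuclei with both Xist and a Y-linked UMI were 0.153 times (0.0615 to 0.315) as many as independent drawing gives. Partial mixing, or doublets among a part of the nuclei, could also leave this ratio low and is not excluded. Mixing among pieces 1 to 3, which have like sex-linked levels, would not show in it. No biological explanation was tested.

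The levels that differ between pieces in rod-like nuclei form the second pattern. Sections of 1 eye are argued against for piece 4, whose Xist, without rod cluster 5, was 21.6 times (16.8 to 28.1) the highest of pieces 1 to 3. Within pieces 1 to 3 the Y-linked sum differed by 1.17 times (0.963 to 1.42). Eyes of the same sex would have like Y-linked levels, so this test could not separate 1 eye from several there. The 47 genes also differed among pieces 1 to 3, by a median of 2.97 times, but no bound for sections of 1 eye was set for them. Thinning gave each nucleus the same weight, and the median ratio of the 47 genes was 4.24 (3.44 to 6.04) after it. The greater weight of nuclei with many UMIs as the whole cause is therefore argued against. Thinning does not change the expected share of a gene within a nucleus, and nuclei kept their class. Other effects of depth, such as those on filtering or naming, were therefore not tested. The dorsal or ventral part of the retina covered is argued against too, since the parts of a piece rich and poor in Opn1sw differed in these genes by a median of 1.09 times (0.9896 to 1.16), while other differences in the plane of section were not tested. Sex as the whole cause is argued against, since pieces 1 to 3, with like Xist and Y-linked levels beside piece 4, differed by a median of 2.97 times (2.68 to 3.65), while differences in animal or genotype stay open and untested, because the labels give the pieces no group.

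Rod transcripts in cone-like nuclei form the third pattern. Free RNA alone, if spread evenly over the classes, is argued against, since the 12 rod markers stood in cone-like nuclei at a median of 9.59 times (quartiles 8.68 and 11.2) their highest level in a class without photoreceptors, with 11 of 12 beyond 2 times and Slc24a1 at 1.20 times (1.14 to 1.27). Free RNA that is denser near rods was not tested. Rod-like nuclei were 51.0% of the neighbours of cone-like and 42.8% of those of RPE-like nuclei. Rod nuclei caught with cone nuclei cannot be told apart from transcripts of the cones themselves: cone-to-rod ratios of the 12 rod markers differed by 2.65 times (2.37 to 2.97), but the bound of 2 set for this test assumed an average rod. Against rod cluster 0 alone (984 nuclei) all ratios lay between 0.562 and 0.865, while against the other rod clusters they spread by 2.61 to 3.94 times, so a mixture with that kind of rod may remain. No biological explanation was tested.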
